A study of Lepidium sativum with 107 samples.

How the data were processed

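RNA of garden cress (Lepidium sativum) seed tissues was hybridised to 1-colour expression arrays, 1 sample to an array. The arrays fell into 27 groups by tissue and stage, with 4 replicates in 26 groups and 3 in the dry seed part that held non-micropylar endosperm and cotyledon tissue. Per the labels' protocols, seeds were kept at 24 °C in continuous light, 100 organs were pooled per sample (50 for cotyledons), and 100 ng of RNA was biotin-labelled with a 3' amplification kit. Each group was taken from the sample labels. The labels do not say that replicates came from separate seed cultures, so p-values measure only the spread between these samples, which may be technical.

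The deposited values are log2 expression, 1 table of 13895 probe sets with 1 column per array, made by the authors with RMA in the affy package, per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a set. It shrinks differences among dim probe sets and holds array totals equal, so changes are relative to the bulk of transcripts. Versions, array design and probe-set definition were not given in the sources used here. The table keys each probe set by an Arabidopsis locus code, 1 probe set to a locus, and does not pair codes with gene names. Gene symbols therefore come from lists fixed beforehand, whose 351 loci include 255 measured here, and a value describes whatever cress transcript bound the probes filed under that code. The table held 47 mitochondrial and 2 chloroplast loci. Values ran from 2.54 to 13.0, with array medians of 4.04 to 4.17 (SD 0.0289). RMA values carry no call of signal over background. A mean level under 3.59, the 25th percentile of all group means, is treated as not clearly above background, and a change from or to such a level is a lower bound, named as one or written as at least (52 of 257 passing values of named genes). A difference between tissues that such a level enters is called approximate, or at most where the level limits the smaller rise. The number of arrays limits the precision.

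All arrays entered 1 limma fit with a mean per group (limma 3.58.1, R 4.3.3, 80 residual and 6.04 prior degrees of freedom), so every comparison shared 1 moderated estimate of the spread. Differences of group means were tested with empirical Bayes moderation and Benjamini-Hochberg adjustment over the 13895 probe sets of each comparison, and passed at an adjusted p under 0.05. An error given after a log2 change is the limma standard error, and an error given after a group level is the SD. The comparisons were testa rupture at 7 h and endosperm rupture at 16 h in micropylar endosperm and radicle, the interactions of rupture with tissue, and the time before testa rupture and between ruptures in both tissues. The time from 3 h to 13 h in the other 2 tissues, pairs of tissues averaged over shared stages, the 2 dry seed parts, the first hour and the stage profiles (an F-test over 9 stages) completed them. For the first hour a transcript had to pass in the same direction in both tissues. Differences between time courses of single genes were tested in the same fit after the values had been seen.

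Lists were tested with camera (preset inter-gene correlation 0.01), adjusted over 336 pairs of 21 lists and 16 comparisons, then repeated with an estimated correlation and with fry. Camera p-values are those with the preset correlation unless stated. For most lists they were smaller than with an estimated correlation. The lists were pectin methylesterases, their inhibitors, expansins, xyloglucan endotransglucosylases, mannanases with glucanases and polygalacturonases, seed storage and oil body proteins, late embryogenesis and ABA-responsive genes, ABA, gibberellin and ethylene genes, touch, wound and defence genes, NADPH oxidases and antioxidant enzymes, heat shock genes, aquaporins, cell cycle genes, photosynthesis genes and storage oil breakdown. Markers of endosperm, seed coat, root with root cap, and cotyledon with shoot covered the neighbouring tissues a dissected sample could hold. The list called late embryogenesis genes for short also held the regulators ABI3, ABI4, ABI5, FUS3 and LEC1.

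Groups, comparisons, lists, all but the last 2 of the alternatives and the rule for named genes were set before the data were examined. The rule took the 6 higher and 6 lower genes with the largest change and no overlap between replicates, up to 4 passing members of each list that passed or was counted, and a panel of 16 germination genes whatever their result. Of the panel, MAN6 and DOG1 are not analysed here, 1 gene is not reported here, and the other 13 make up the counts given for the panel. Of codes without a listed symbol, only 2 that rose and 2 that fell are printed.

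The alternatives were an intensity trend with robust moderation, no probe sets under a brightness limit of 3.59 (748 fewer), centring on the brighter probe sets, quantile normalization, only the arrays of the comparison, a replicate block, array weights, a 2-fold minimum, and each array left out in turn. After the data had been seen, the leading axis of the spread within groups (13.8% of it) was added as a covariate, and 4 arrays farther than an SD of 0.3 from their group mean were left out. Taking the best or the mean probe set per gene was not run, since each locus had 1 probe set. A list of ribosomal proteins was left out for want of gene descriptions.

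The fit was tested on simulated data, with 200 of 13895 probe sets changed in 10 draws. Residuals were shuffled over all groups, so unequal spread between groups was not part of this test. For a comparison of 4 against 4 arrays it recovered 32.5% of changes of 0.5, 91.8% of changes of 1 and 100% of changes of 2 on the log2 scale, with 4.84% of calls false. For the interaction these shares were 11.6%, 66.0% and 98.8%, with 5.64% of calls false. For the mean over 3 stages (micropylar against other endosperm) they were 85.5%, 99.7% and 100%. In the dry parts they were 30.9%, 84.8% and 100%, with 7.90% of calls false. For the profile over 9 stages they were 33.4%, 91.9% and 100%. For micropylar endosperm against radicle they were 99.4%, 100% and 100%. A list shifted by 0.5 passed camera in 10 of 10 draws; unshifted it passed in 1 of 10, and 7 of 200 other lists passed, against 0 of 200 with an estimated correlation.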

Results

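Transcript levels were measured in germinating seeds of garden cress (Lepidium sativum), in which the seed coat (testa) splits first and the endosperm around the radicle tip ruptures later. Micropylar endosperm, the cap over the radicle tip, and radicle with lower hypocotyl were sampled at 9 stages from 1 h to 16 h of imbibition, the 7 h and 16 h harvests being sorted into seeds before and after rupture. Non-micropylar endosperm and cotyledons were sampled at 3 h, at 7 h with the testa intact and at 13 h. Whole dry seeds and 2 dry seed parts were the remaining groups. There were 27 groups of arrays, 4 per group except 3 for the dry part with cotyledon tissue, and their number limits the precision. Values are log2 expression, and the first 3 principal components of all arrays held 35.0%, 18.1% and 10.2% of the variance.

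The comparison of 7 h seeds with ruptured and intact testa asked what accompanies testa rupture in tissue of 1 age. In micropylar endosperm, 9 of 19 xyloglucan endotransglucosylases, enzymes that cut and rejoin wall xyloglucan, rose after rupture and none fell (10 rose adjusted over the list alone). XTH18 (AT4G30280) rose 5.48-fold, from 4.59 ± 0.98 to 7.05 ± 0.50 (SD, n = 4 each), and XTH4 (AT2G06850), XTH16 (AT3G23730) and XTH6 (AT5G65730) rose by 2.19 ± 0.21, 2.13 ± 0.35 and 2.09 ± 0.32 on the log2 scale. Of 11 heat shock genes, most of which encode chaperones, 6 fell (6 adjusted over the list alone), among them HSP17.4 (AT3G46230, -1.95 ± 0.23), HSP101 (AT1G74310, -1.37 ± 0.24) and HSP90.1 (AT5G52640, -1.32 ± 0.24). Of 16 late embryogenesis and ABA-responsive genes, many of which protect cells during seed drying, 3 fell (3 adjusted over the list alone): ECP63 (AT2G36640, -1.92 ± 0.21, a lower bound), RAB18 (AT5G66400, -1.37 ± 0.22) and LEA14 (AT1G01470, -0.71 ± 0.20). TIP3;1 (AT1G73190), an aquaporin of seed vacuoles, fell by 1.98 ± 0.25, and the unlisted AT5G09970 fell from 7.48 ± 0.27 to 5.41 ± 0.70 (SD, n = 4 each). With camera, the adjusted p was 7.29e-15 for the xyloglucan enzymes, 6.45e-07 for heat shock genes and 8.38e-06 for late embryogenesis genes. With an estimated correlation camera gave adjusted p = 6.58e-06, 0.00422 and 0.00782, in the same order. Of 47 mitochondrial loci 9 fell as well (median -0.17).

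In total 880 of 13895 probe sets passed in limma, 506 higher and 374 lower. Of the 13 panel genes, XTH18 and GASA6 (AT1G74670, a gibberellin-regulated gene, 1.21 ± 0.32) rose, RGL2 (AT3G03450, a repressor of gibberellin signalling, -0.70 ± 0.20) and CYP707A2 (AT2G29090, an ABA 8'-hydroxylase, -0.83 ± 0.26) fell, and 9 did not pass (-0.34 to 0.60), the highest being XTH19 (AT4G30290), which was at 1.13 and past the threshold without replicate 2 of the ruptured seeds. The count was 464 without replicate 4 of the ruptured and 573 without replicate 4 of the intact seeds. It was 2328 with array weights. On the arrays of the comparison alone 1124 passed, 523 higher and 601 lower, so fallers were then the majority. GASA6 did not pass without replicate 2 of the intact seeds (1.05), LEA14 without replicate 1 (-0.65) or 2 (-0.48) of the ruptured ones, and RGL2 and CYP707A2 failed in 3 and 6 of the 8 fits with 1 array left out.

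In the radicle at testa rupture, 5 of 19 xyloglucan endotransglucosylases rose and none fell (6 rose adjusted over the list alone), with XTH8 (AT1G11545) at 2.13 ± 0.31, XTH33 (AT1G10550) at 2.03 ± 0.30, XTH16 at 1.52 ± 0.35 and XTH4 at 1.32 ± 0.21. HSP17.4 fell by 1.91 ± 0.23 with 4 other heat shock genes of 11 (6 adjusted over the list alone), of which HSP101, HSP17.6II (AT5G12020) and HSP22.0 (AT4G10250) were lost in 6, 5 and 5 of the 8 fits with 1 array left out. None of 16 late embryogenesis genes passed singly, although 4 fell adjusted over the list alone and their median was -0.27. PME44 (AT4G33220, a pectin methylesterase, at least 0.47 ± 0.09) was the 1 riser among 15 pectin methylesterases (1 adjusted over the list alone), TIP3;1 fell by 1.27 ± 0.25 and EXPA1 (AT1G69530), a wall-loosening expansin, fell by 0.99 ± 0.22. Of 47 mitochondrial loci 8 fell and 1 rose (median -0.22).

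In camera the radicle had adjusted p = 4.66e-07 for the xyloglucan enzymes, 5.69e-09 for heat shock genes, 0.000271 for late embryogenesis genes and 0.0079 for pectin methylesterases. The last did not hold, adjusted p = 0.068 with an estimated correlation, nor without replicate 4. In the radicle 237 probe sets passed, 88 higher and 149 lower, falling to 111 without replicate 2 of the intact and 120 without replicate 3 of the ruptured seeds. None of the 13 panel genes passed (-0.66 to 0.47). Both tissues shared 36 risers, with 3.21 for independent lists (one-sided Fisher's exact p = 5.07e-29), and 67 fallers, with 4.01 for independent lists (p = 4.98e-66), and no probe set passed in opposite directions. Changes correlated across genes at r = 0.52, genes not being independent replicates.

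Testing the difference between tissues directly, the change of XTH18 was more positive in micropylar endosperm than in radicle by 2.35 ± 0.43, that of XTH6 by 2.21 ± 0.45 and that of XTH24 (AT4G30270) by 0.81 ± 0.20, and none of the other 16 xyloglucan enzymes passed (6 of 19 adjusted over the list alone, 5 higher and 1 lower). The unlisted AT5G09970, which fell in the endosperm, was at 0.08 in radicle, a difference of -2.15 ± 0.25. ECP63 had a difference of -1.45 ± 0.30, but in radicle it was at 3.59 before rupture and 3.12 after it, near or under the brightness limit, so a fall there could not be measured. The differences of XTH18 and XTH24 are approximate, both being under the brightness limit in radicle. The list passed camera with adjusted p = 0.000413, and 60 probe sets passed, 52 with the more positive change in endosperm. Of the panel, XTH18 was the 1 gene to pass (the other 12 lay between -0.63 and 0.81). The count was 34 without replicate 4 of the ruptured and 40 without replicate 2 of the intact micropylar endosperm. XTH24 was lost in 9 of 16 fits with 1 array left out, and XTH18 was not past the threshold on the 16 arrays alone.

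Endosperm rupture was compared within the 16 h harvest. In micropylar endosperm, 3 of 17 ethylene genes rose and none fell (3 adjusted over the list alone), among them the response genes EBF2 (AT5G25350, 0.79 ± 0.22, n = 4 each) and ERS1 (AT2G40940, 0.38 ± 0.12). Of 15 touch, wound and defence genes 3 rose and none fell (4 adjusted over the list alone): the defence regulators WRKY33 (AT2G38470, 1.35 ± 0.20) and ERF5 (AT5G47230, 0.92 ± 0.20), and PR5 (AT1G75040, 0.47 ± 0.12). ADPG2 (AT2G41850), a polygalacturonase of separating tissues, rose by 1.57 ± 0.19 and the mannanase MAN2 (AT2G20680) by 0.59 ± 0.12, the 2 of 8 mannanases, glucanases and polygalacturonases that passed (2 adjusted over the list alone). XTH30 (AT1G32170, at least 1.04 ± 0.17), XTH18 (1.00 ± 0.30) and XTH24 (0.48 ± 0.14) rose and XTH5 (AT5G13870, -0.90 ± 0.25, a lower bound) fell among 19 xyloglucan enzymes (10 adjusted over the list alone). PER1 (AT1G48130), a seed peroxiredoxin, fell by 2.19 ± 0.26, and the unlisted AT1G78000 rose from 4.45 ± 0.18 to 8.03 ± 0.18 (SD, n = 4 each).

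With camera, adjusted p was 0.000187 for the xyloglucan enzymes, 0.00639 for touch genes and 0.0475 for ethylene genes in micropylar endosperm at endosperm rupture. Touch genes had adjusted p = 0.128 with an estimated correlation and were lost without replicate 2. Ethylene genes had adjusted p = 0.068 with an estimated correlation and were lost without replicate 1, 2 or 4 and after quantile normalization or with a fixed replicate block. In all 598 probe sets passed, 464 higher and 134 lower. Of the panel, XTH18 rose, RGL2 fell (-0.77 ± 0.20) and 11 did not pass (-0.26 to 1.00), although XTH19 did without replicate 1 of the intact (1.44) or replicate 3 of the ruptured seeds (1.22). With the 8 arrays fitted alone 30 probe sets passed, and none of the genes named here from the lists was still past the threshold. Without replicate 4 of the ruptured seeds 351 passed and PR5 (0.25) and RGL2 (-0.65) did not, without replicate 4 of the intact seeds 383 passed and PR5 (0.41) and XTH5 (-0.57) did not, and without replicate 2 of the ruptured seeds ERF5 was lost (0.62). EBF2, ERS1 (0.24 without replicate 4 of the ruptured seeds), XTH18, XTH5 and XTH24 were lost in 3 to 5 of the 8 fits with 1 array left out.

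In the radicle at endosperm rupture, 3 of 15 pectin methylesterases rose and none fell (4 adjusted over the list alone): PME51 (AT5G09760, 0.83 ± 0.17), PME34 (AT3G49220, 0.58 ± 0.12) and PME44 (0.51 ± 0.09). ACO1 (AT2G19590), an ACC oxidase of ethylene synthesis, rose by 0.99 ± 0.20 (n = 4 each). LEA7 (AT1G52690), a late embryogenesis gene, fell by 2.03 ± 0.32, PER1 by 1.19 ± 0.26 and RGL2 by 1.00 ± 0.20. MCM7 (AT4G02060), a subunit of the replicative DNA helicase, rose by 1.03 ± 0.23, and the unlisted AT4G24150 fell from 6.86 ± 0.33 to 3.65 ± 0.18 (SD, n = 4 each).

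Pectin methylesterases passed camera in this radicle comparison with adjusted p = 0.00781, but adjusted p = 0.068 with an estimated correlation, and they were lost without replicate 4. In all 756 probe sets passed, 496 higher and 260 lower. Of the panel ACO1 rose, RGL2 fell and 11 did not pass (-0.10 to 0.63), although PME3 (AT3G14310, 0.35) and GASA6 (0.99) did without replicate 1 of the intact seeds. On the 8 arrays alone 266 passed, not including ACO1, MCM7, PER1, PME34 or PME44, and the count was 502 without replicate 2 and 1148 without replicate 1 of the intact seeds. Both tissues shared 77 risers, with 16.6 for independent lists (one-sided Fisher's exact p = 1.05e-30), and 27 fallers, with 2.51 for independent lists (p = 1.46e-20), 2 and 1 passed in opposite directions, and r across genes was 0.34. Testa and endosperm rupture shared 67 risers and 9 fallers in micropylar endosperm, with 16.9 and 3.61 for independent lists, while 7 rose at the first and fell at the second, 5 did the opposite and r across genes was 0.18.

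**Figure D1:**
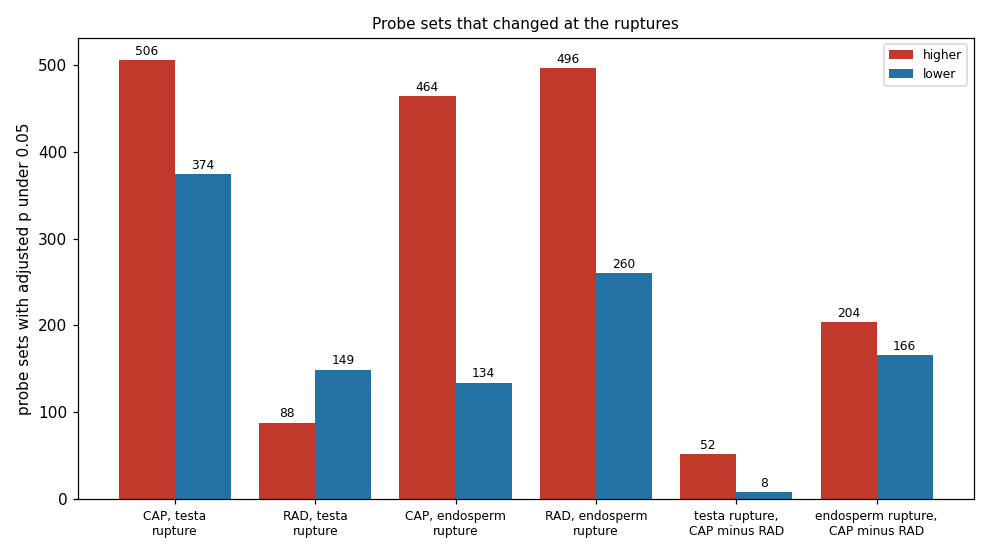
Bars give the number of probe sets with an adjusted p under 0.05 (y axis, from 0) that were higher or lower after testa rupture at 7 h and endosperm rupture at 16 h, in micropylar endosperm (CAP) and radicle (RAD) with 4 arrays in each group, and of those whose change differed between the tissues (CAP minus RAD). At testa rupture 880 passed in micropylar endosperm and 237 in radicle, and at endosperm rupture 598 and 756.

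The difference between tissues at endosperm rupture passed for WRKY33, which rose more in micropylar endosperm by 1.23 ± 0.28, and for ADPG2 (1.17 ± 0.27) and XTH30 (0.91 ± 0.24). WRKY33 and XTH30 lay under the brightness limit in radicle, so their differences are approximate. MCM7, which rose in radicle, was at -0.32 in micropylar endosperm, a difference of -1.35 ± 0.32. WRKY33 was the 1 of 15 touch, wound and defence genes to pass (2 adjusted over the list alone). The list had adjusted p = 0.0105 in camera but adjusted p = 0.16 with an estimated correlation, and was lost without replicate 2 or 4. Of 370 probe sets that passed, 204 had the more positive change in micropylar endosperm, and none of the 13 panel genes passed (-0.86 to 0.94), although ACO1 did without replicate 1 of the intact radicle (-1.06). On the 16 arrays alone 41 passed, not including WRKY33, ADPG2, XTH30 or MCM7, and XTH30 was lost in 3 of 16 fits with 1 array left out.

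The time before testa rupture was followed from 1 h to 7 h in seeds with intact testa. In micropylar endosperm 6 of 14 expansins rose and none fell (6 adjusted over the list alone), with EXPA2 (AT5G05290) up 37.6-fold (5.23 ± 0.31), EXPA9 (AT5G02260) by 3.74 ± 0.27, EXPA1 by 3.00 ± 0.22 and EXPA10 (AT1G26770) by 2.35 ± 0.21. Of 19 xyloglucan enzymes 12 rose and none fell (12 adjusted over the list alone), led by XTH33 (6.75 ± 0.30), XTH16 (3.83 ± 0.35) and XTH19 (3.55 ± 0.34). Of 11 seed storage and oil body proteins 8 fell (8 adjusted over the list alone), with the oleosin OLEO1 (AT4G25140) at -3.36 ± 0.22 and the cruciferin CRA1 (AT5G44120) at -2.67 ± 0.24. Of the late embryogenesis list, which also holds regulators, 11 of 16 genes fell and 1 rose (12 adjusted over the list alone), with EM1 (AT3G51810) at -4.22 ± 0.33 and RAB18 at -2.69 ± 0.22. Of 20 ABA genes 9 rose and 1 fell (10 adjusted over the list alone): CYP707A3 (AT5G45340), which breaks ABA down, rose by 2.18 ± 0.27, NCED5 (AT1G30100), which makes it, by 2.01 ± 0.18, and the signalling kinase OST1 (AT4G33950) and receptor PYR1 (AT4G17870) by 1.82 ± 0.17 and 1.67 ± 0.15. The values of EXPA9, EXPA10, XTH33, XTH19, CRA1 and NCED5 are lower bounds. That of XTH16 may be one too, since only replicate 2 at 1 h was over the brightness limit. Of 47 mitochondrial loci 32 fell (median -0.74).

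These lists in micropylar endosperm had adjusted p = 8.66e-06, 1.87e-05, 2.42e-05, 0.000194 and 0.0209 in camera, in the order given. The panel gave 7 risers, among them GASA6 (at least 4.25 ± 0.32), RGL2 (2.77 ± 0.20) and MAN7 (AT5G66460, a mannanase, 0.36 ± 0.10), while the endosperm extensin EPR1 (AT2G27380, -2.94 ± 0.22) and ABI5 (AT2G36270, an ABA-response regulator, -1.12 ± 0.17) fell and 4 did not pass (-0.23 to 0.38). XTH18 rose by at least 1.23 ± 0.30, or 0.76 without replicate 1 at 7 h. In all 5313 probe sets passed, 2321 higher and 2992 lower.

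In the radicle over the same hours, 8 of 19 xyloglucan enzymes rose and none fell (8 adjusted over the list alone), with XTH16 at 3.22 ± 0.35 and XTH4 at 2.28 ± 0.21. Storage and oil body proteins fell in 9 of 11 (9 adjusted over the list alone), with CRA1 at -3.44 ± 0.24 and OLEO1 at -2.41 ± 0.22. Of the late embryogenesis list, which also holds regulators, 11 of 16 genes fell and 2 rose (13 adjusted over the list alone), with ECP63 at -2.65 ± 0.21 and EM1 at -2.04 ± 0.33. PIN2 (AT5G57090), an auxin exporter of root tissue, rose by 2.46 ± 0.28 and RGL2 by 2.60 ± 0.20, the values of XTH16, XTH4, OLEO1 and PIN2 being lower bounds, while 24 of 47 mitochondrial loci fell and 1 rose (median -0.48). Storage proteins passed camera with adjusted p = 1.08e-05. The xyloglucan enzymes had 0.00147 in camera but adjusted p = 0.0621 with an estimated correlation, and late embryogenesis genes 0.0109 but adjusted p = 0.133 with an estimated correlation. In all 5494 probe sets passed, 2300 higher and 3194 lower. Of the panel, RGL2 rose, EPR1 (-0.71 ± 0.22) and ABI5 (-0.55 ± 0.17) fell and 10 did not pass (-0.26 to 0.53), ABI5 being at -0.33 and lost without replicate 2 at 1 h.

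Tested in both tissues together, the change of EXPA2 before testa rupture was more positive in micropylar endosperm than in radicle by 5.43 ± 0.44 (adjusted p = 3.98e-17 in limma), XTH19 by 3.35 (adjusted p = 2.08e-07) and GASA6 by 3.72 (adjusted p = 2.29e-09), all approximate because levels of each under the brightness limit enter them. EM1 (-2.17, adjusted p = 0.000872) and EPR1 (-2.23, adjusted p = 1.99e-07) fell more in the endosperm. For XTH16 (approximately 0.61, adjusted p = 0.523) and RGL2 (0.17, adjusted p = 0.797) no difference was detected. The level of XTH16 at 1 h was under the brightness limit in radicle. In endosperm at 1 h only replicate 2 was over that limit, so a difference in either direction could be missed. Both tissues shared 1365 risers and 1858 fallers, with 384.2 and 687.8 for independent lists, 19 and 27 passed in opposite directions, and r across genes was 0.76.

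Between the ruptures, from 7 h with ruptured testa to 16 h with intact endosperm, 9 of 16 storage oil breakdown genes rose in micropylar endosperm and none fell (9 adjusted over the list alone). PCK1 (AT4G37870), which acts on the way from stored oil to sugar, rose by 1.74 ± 0.18, and ACX1 (AT4G16760) and KAT2 (AT2G33150), of fatty acid beta-oxidation, by 1.48 ± 0.19 and 1.26 ± 0.16. Xyloglucan enzymes fell in 8 of 19 and none rose (11 adjusted over the list alone, 9 lower and 2 higher), with XTH33 at -2.93 ± 0.30 and XTH16 at -2.05 ± 0.35. Late embryogenesis genes fell in 5 of 16 (6 adjusted over the list alone), RAB18 by 3.01 ± 0.22 and LEA7 by 2.51 ± 0.32. Gibberellin genes fell in 5 of 22 (6 adjusted over the list alone, 5 lower and 1 higher): GASA6 by 2.95 ± 0.32, GASA14 (AT5G14920) by 1.63 ± 0.15 and RGL2 by 1.41 ± 0.20, the first 2 being gibberellin-regulated and RGL2 a repressor. Of 47 mitochondrial loci 9 fell (median -0.17).

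Camera gave adjusted p = 1.28e-07 for oil breakdown, 3.98e-05 for xyloglucan enzymes, 0.000388 for late embryogenesis genes and 0.0079 for gibberellin genes, and 2212 probe sets passed, 1156 higher and 1056 lower. Of the panel, 7 fell, among them EPR1 (-1.25 ± 0.22), CYP707A2 (-1.50 ± 0.26) and MAN7 (-0.46 ± 0.10), and 6 did not pass (-0.14 to 0.37). On the 8 arrays alone 1454 passed, without XTH18 and XTH19, which fell by 1.40 ± 0.30 and 1.84 ± 0.34.

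In the radicle between the ruptures, 7 of 16 cell cycle and DNA replication genes rose and none fell (9 adjusted over the list alone), among them the replicative helicase subunits MCM4 (AT2G16440, 2.15 ± 0.25), MCM7 (1.99 ± 0.23), MCM2 (AT1G44900, at least 1.99 ± 0.22) and MCM5 (AT2G07690), which went from 4.78 ± 0.11 to 6.98 ± 0.48 (SD, n = 4 each). Late embryogenesis genes fell in 4 of 16 (4 adjusted over the list alone), with RAB18 at -3.17 ± 0.22 and EM1 at -3.16 ± 0.33, and heat shock genes in 3 of 11 (5 adjusted over the list alone), with HSP17.6II at -2.94 ± 0.36 and HSP17.4 at -1.41 ± 0.23, a lower bound. Oil breakdown genes rose in 5 of 16 and none fell (9 adjusted over the list alone), with the glyoxylate cycle enzyme ICL (AT3G21720) at 1.15 ± 0.20. Cell cycle genes had adjusted p = 2.13e-09 and late embryogenesis genes 3.14e-05 in camera. Heat shock genes had 0.00155 in camera but adjusted p = 0.068 with an estimated correlation, and oil breakdown 1.87e-05 but adjusted p = 0.0852 with an estimated correlation. In all 1648 probe sets passed, 950 higher and 698 lower, and 2 mitochondrial loci rose and 1 fell (median -0.05).

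Of the panel, GASA6 (2.48 ± 0.32) and ACO1 (0.60 ± 0.20) rose in the radicle between the ruptures, RGL2 fell (-1.11 ± 0.20) and 10 did not pass (-0.47 to 0.16). ACO1 was lost in 4 of 8 fits with 1 array left out, its value being 0.25 without replicate 1 at 16 h. GASA6 moved in opposite directions in the tissues, the difference being -5.43 (adjusted p = 2.31e-16 in limma), and MAN7, which fell in micropylar endosperm, was at 0.09 in radicle (difference -0.55, adjusted p = 0.00378). No difference was detected for RAB18 (0.15, adjusted p = 0.861) or PCK1 (0.70, adjusted p = 0.0701). The tissues shared 258 risers and 203 fallers, with 79.0 and 53.1 for independent lists (one-sided Fisher's exact p = 5.59e-73 and 4.86e-69), while 16 rose in micropylar endosperm and fell in radicle and 34 did the opposite.

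**Figure D2:**
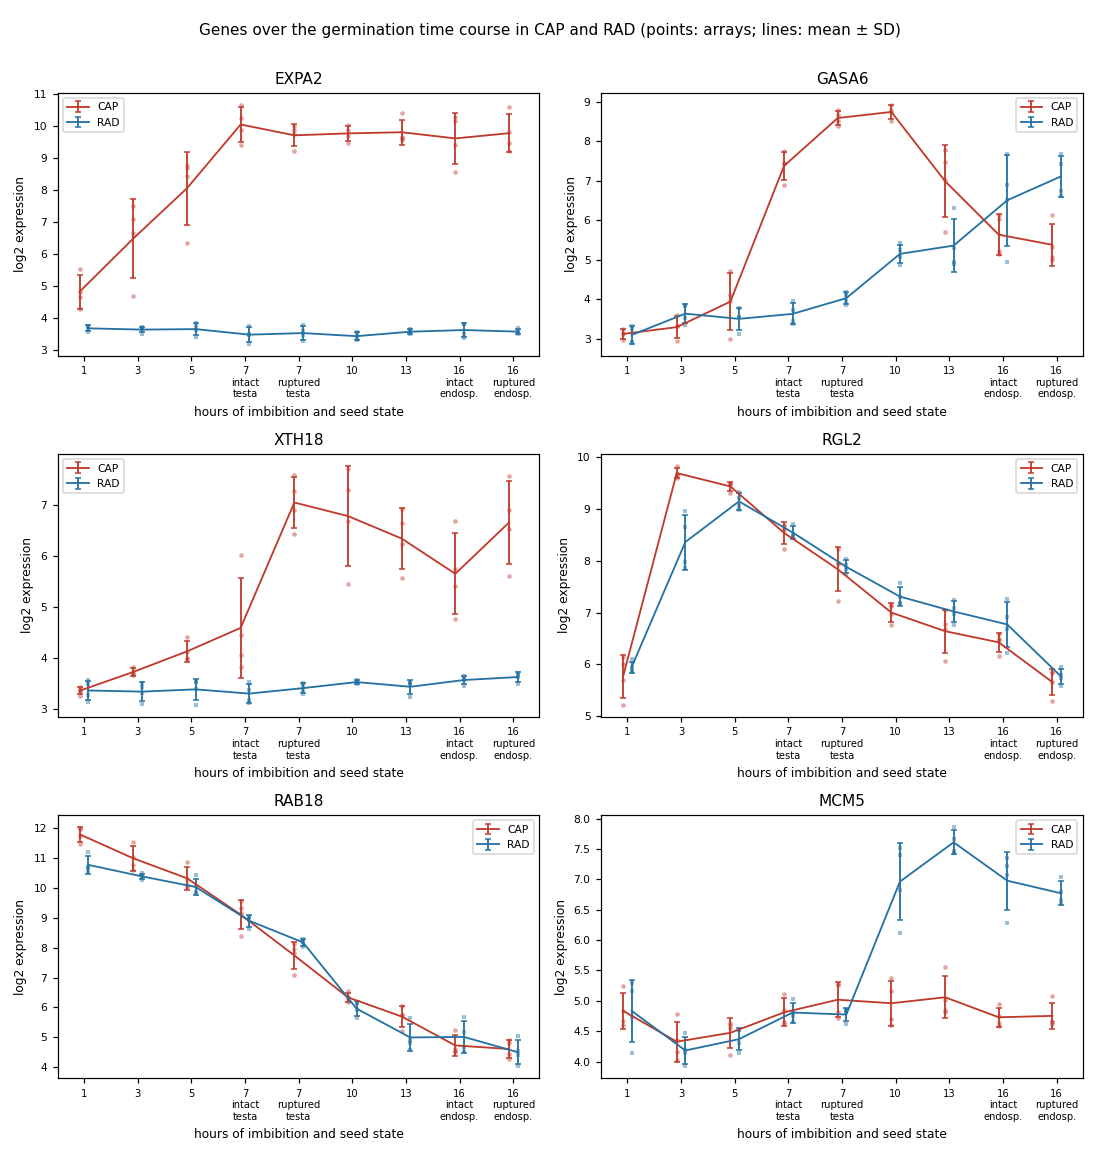
Log2 expression (y axis) of 6 named genes across the 9 stages (x axis) in micropylar endosperm (CAP) and radicle (RAD), with points for arrays, lines for means and bars for the SD over 4 arrays. EXPA2 went from 4.82 at 1 h to 10.05 at 7 h with intact testa in micropylar endosperm and lay between 3.43 and 3.67 in radicle, and MCM5 reached 7.61 at 13 h in radicle.

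From 3 h to 13 h in non-micropylar endosperm, xyloglucan enzymes rose in 13 of 19 and fell in 1 (15 adjusted over the list alone), with XTH33 at 5.65 ± 0.30 and XTH16 at no less than 5.63 ± 0.35, and expansins rose in 6 of 14 (6 adjusted over the list alone), with EXPA2 up 65.7-fold (6.04 ± 0.31). Late embryogenesis genes fell in 14 of 16 (14 adjusted over the list alone), RAB18 by 5.18 ± 0.22, and heat shock genes in 10 of 11 (10 adjusted over the list alone), HSP17.4 by at least 4.25 ± 0.23. Of 20 ABA genes 12 fell and 1 rose (15 adjusted over the list alone, 12 lower and 3 higher), with CYP707A2 at -2.29 ± 0.26 and the ABA synthesis gene NCED2 (AT4G18350) at -1.75 ± 0.18. Oil breakdown genes rose in 11 of 16 and fell in 1 (13 adjusted over the list alone), KAT2 by 2.11 ± 0.16, while storage and oil body proteins fell in 7 of 11 (7 adjusted over the list alone), OLEO1 by at least 3.75 ± 0.22. Of 47 mitochondrial loci 35 fell (median -1.25).

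Camera gave adjusted p = 5.07e-06 for the xyloglucan enzymes, 4.49e-09 for late embryogenesis, 5.67e-06 for heat shock and 0.0082 for ABA genes in non-micropylar endosperm. Expansins had 0.0305, with adjusted p = 0.133 with an estimated correlation, and were lost without replicate 1 or 3. Storage proteins had 0.000562, with adjusted p = 0.0785 with an estimated correlation, and oil breakdown 2.8e-05, with adjusted p = 0.0944 with an estimated correlation. In all 5459 probe sets passed, 2690 higher and 2769 lower. Of the panel 6 rose, among them GASA6 (at least 4.87 ± 0.32) and MAN7 (0.40 ± 0.10), 4 fell, among them RGL2 (-2.07 ± 0.20) and EPR1 (-1.97 ± 0.22), and 3 did not pass (-0.18 to 0.11).

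Over the same hours in cotyledons, XTH16 rose by 5.49 ± 0.35 among 9 of 19 xyloglucan enzymes, none of which fell (10 adjusted over the list alone). EM1 fell by 5.29 ± 0.33 among 10 of 16 late embryogenesis genes (10 adjusted over the list alone), CRA1 by 3.71 ± 0.24 among 6 of 11 storage proteins (6 adjusted over the list alone), and HSP17.4 by 3.24 ± 0.23 among 9 of 11 heat shock genes (9 adjusted over the list alone). Of 9 aquaporins 3 fell (3 adjusted over the list alone), the vacuolar TIP3;1 by 2.49 ± 0.25 and TIP3;2 (AT1G17810) by 1.66 ± 0.20 and the plasma membrane PIP1;2 (AT2G45960) by 0.52 ± 0.16. FIL (AT2G45190) and AS1 (AT2G37630), regulators of leaf development, rose by 1.38 ± 0.21 and 1.22 ± 0.24, and 36 of 47 mitochondrial loci fell (median -1.96).

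Camera gave adjusted p = 4.81e-05, 5.06e-12, 1.58e-08 and 2.94e-08 for the first 4 lists in cotyledons. Aquaporins had 0.0226, with adjusted p = 0.0662 with an estimated correlation, and were lost without replicate 2. In all 3529 probe sets passed, 1797 higher and 1732 lower, or 1793 on the 8 arrays alone. Of the panel GASA6 rose (at least 0.84 ± 0.32, lost in 7 of 8 fits with 1 array left out), ABI5 (-0.59 ± 0.17) and CYP707A2 (-0.92 ± 0.26) fell and 10 did not pass (-0.48 to 0.35), although GA3OX1 (AT1G15550) did without replicate 1 at 3 h (0.34) or replicate 3 at 13 h (0.37) and RGL2 without replicate 1 at 13 h (-0.63); CYP707A2 was lost without replicate 1 at 3 h (-0.70) or replicate 2 at 13 h (-0.64), and ABI5 on the 8 arrays alone. Against cotyledons, EXPA2 rose more in non-micropylar endosperm by 5.95 (adjusted p = 9.65e-20 in limma) and RAB18 fell more by 1.47 (adjusted p = 0.000215). XTH33 rose more by at most 4.60 (adjusted p = 1.56e-14), its level in cotyledons at 3 h being under the brightness limit. XTH16 showed no detected difference (approximately 0.14, adjusted p = 0.904). Its level in non-micropylar endosperm at 3 h was under the limit, so a greater rise there could be missed. PCK1 moved in opposite directions, with a difference of 3.47. The tissues shared 1101 risers and 1180 fallers, with 347.9 and 345.2 for independent lists, and 22 and 46 passed in opposite directions.

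Averaged over the 9 stages, micropylar endosperm was compared with radicle to describe tissue identity. Of 14 expansins 8 were higher in the endosperm and 4 lower (12 adjusted over the list alone), EXPA2 being at least 34.5-fold higher (5.11 ± 0.10 on the log2 scale, with a mean level of 3.57 in radicle), and XTH33 was higher by 3.95 ± 0.10. EPR1 was higher by 2.26 ± 0.08, and among 4 endosperm markers 2 were higher and 1 lower (4 adjusted over the list alone, 3 higher), the lower one being ALE1 (AT1G62340, -0.14 ± 0.04), at 3.23 and 3.37 dim in both tissues. Oil breakdown genes were higher in 15 of 16 (15 adjusted over the list alone), with the peroxisomal transporter PXA1 (AT4G39850) at 1.67 ± 0.09 and ICL at 1.60 ± 0.07. PIN2 was lower in the endosperm by 1.69 ± 0.09, XTH5 by 1.93 ± 0.08 and the D-type cyclin CYCD2;1 (AT2G22490) by 1.32 ± 0.07.

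Between these tissues oil breakdown had adjusted p = 2.13e-09 and endosperm markers 0.0106 in camera. Expansins had 0.0369, with adjusted p = 0.15 with an estimated correlation. EXPA2 belongs to both the endosperm markers and the expansins, so the results of these lists are not independent. In all 9137 probe sets passed, 3967 higher in micropylar endosperm and 5170 lower. The score on the leading axis of the spread within groups also differed between the tissues, with stage means of 5.44 to 21.5 in micropylar endosperm and -15.8 to 0.254 in radicle. With it as a covariate 6530 passed, 5546 of them among the 9137, PXA1 was at 1.10 and ALE1 at -0.07 did not pass.

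Over 3 shared stages, micropylar endosperm was set against the rest of the endosperm. Xyloglucan enzymes were higher at the micropyle in 9 of 19 and lower in none (10 adjusted over the list alone, 9 higher and 1 lower), with XTH33 at 1.76 ± 0.18 and XTH19 at 1.13 ± 0.20, and EXPA2 was higher by 0.87 ± 0.18. Late embryogenesis genes were lower in 6 of 16 (6 adjusted over the list alone), RAB18 by -0.92 ± 0.13, and storage proteins in 4 of 11 (4 adjusted over the list alone), OLEO1 by -0.69 ± 0.12. Of 14 root and root cap markers 3 were higher and none lower (3 adjusted over the list alone): PIN2 (at least 0.64 ± 0.16), the auxin importer AUX1 (AT2G38120, 0.55 ± 0.12) and SMB (AT1G79580, a root cap regulator, at least 0.47 ± 0.08). Camera gave adjusted p = 8.66e-06, 0.000121 and 0.00746 for xyloglucan, late embryogenesis and root lists, while storage proteins had 0.0149, with adjusted p = 0.247 with an estimated correlation. In all 1895 probe sets passed, 897 higher and 998 lower, and PIN2 was lost without replicate 2 (0.45).

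Radicle was set against cotyledons over the same 3 stages. Cell cycle genes were higher in radicle in 9 of 16 and lower in none (10 adjusted over the list alone), with MCM5 at 1.45 ± 0.12 and CYCD2;1 at 1.44 ± 0.12, and root markers in 9 of 14 (10 adjusted over the list alone), with PIN2 at 2.01 ± 0.16 and the root stem cell regulator PLT1 (AT3G20840) at 0.90 ± 0.11, both lower bounds. Oil breakdown genes were lower in radicle in 13 of 16 and higher in 1 (14 adjusted over the list alone), with the peroxisomal malate dehydrogenase PMDH1 (AT2G22780) at -1.31 ± 0.16 and PCK1 the higher one at 0.82 ± 0.10. FIL was lower by -2.45 ± 0.12, a lower bound, and the photosystem protein PSBR (AT1G79040) by -1.45 ± 0.11. Camera gave adjusted p = 3.98e-05 for cell cycle genes and 0.000494 for root markers. Oil breakdown had 0.00118, with adjusted p = 0.231 with an estimated correlation. In all 5118 probe sets passed, 2555 higher and 2563 lower.

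In dry seeds, the part with radicle and micropylar endosperm (4 arrays) was set against the part with non-micropylar endosperm and cotyledon tissue (3 arrays). FIL was 4.17-fold lower at the radicle end (-2.06 ± 0.23), PSBR lower by -1.27 ± 0.21 and RCA (AT2G39730, which activates Rubisco) by -1.09 ± 0.15, while the storage albumin SESA5 (AT5G54740) was higher by 1.57 ± 0.39. Whole dry seeds had SESA5 at 6.31 ± 1.64, above 5.25 ± 0.73 at the radicle end and 3.67 ± 0.29 at the cotyledon end (SD). The seed end may thus not be the only source of that difference. Photosynthesis genes were lower in 3 of 9 (4 adjusted over the list alone), and aquaporins in 3 of 9 (5 adjusted over the list alone), the plasma membrane PIP1;1 (AT3G61430) by -1.25 ± 0.28, while TIP1;1 (AT2G36830) and TIP3;2 were lost in 4 and 5 of the 7 fits with 1 array left out. Photosynthesis genes had adjusted p = 0.0079 and aquaporins 0.0135 in camera, both lost without replicate 4. In all 1340 probe sets passed, 563 higher and 777 lower, or 623 on the 7 arrays alone.

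The first hour was followed from the dry radicle end to micropylar endosperm and radicle at 1 h. CRA1, a 12S seed storage globulin, fell from 8.43 ± 0.10 to 6.25 ± 0.75 in endosperm (-2.18 ± 0.24) and to 7.36 ± 0.18 in radicle (-1.08 ± 0.24; SD of levels, n = 4 each), the radicle change not being past the threshold on its own arrays. The mitochondrial locus ATMG00520 rose from 4.37 ± 0.43 to 7.08 ± 0.80 and 6.82 ± 0.70. Mitochondrial loci rose in 22 of 47 in endosperm (median 0.67) and in 9 of 47 in radicle (median 0.33), and all 9 rose in both tissues. Both tissues shared 79 probe sets, 21 higher and 58 lower, of 1136 that passed in endosperm and 408 in radicle, with 8.96 and 7.74 for independent lists, and 16 passed in opposite directions.

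**Figure D3:**
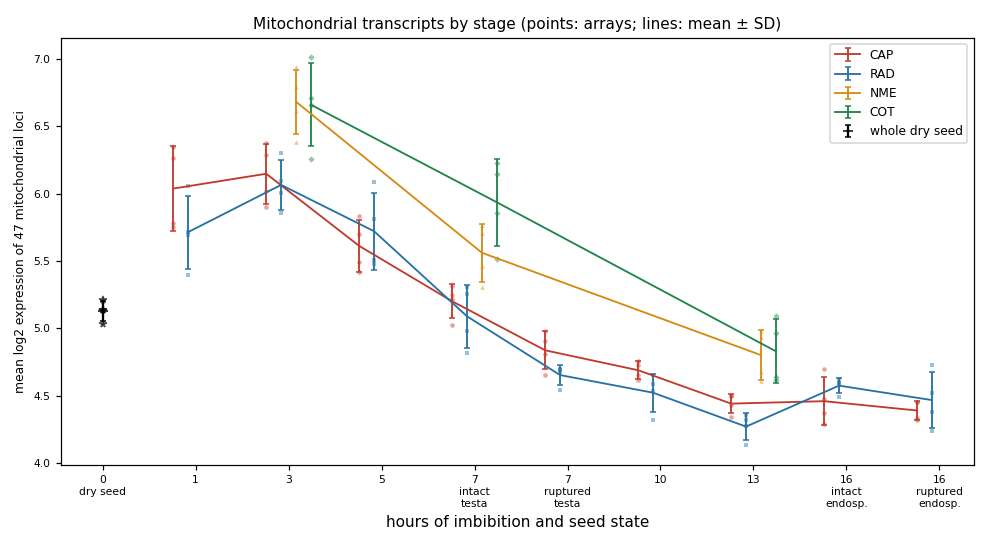
Points give the mean log2 expression of 47 mitochondrial loci on each array (y axis), lines the group means and bars the SD, across stages (x axis) in micropylar endosperm (CAP), radicle (RAD), non-micropylar endosperm (NME), cotyledons (COT) and whole dry seeds. Group means went from 5.13 in whole dry seeds to between 6.07 and 6.68 at 3 h and between 4.27 and 4.83 at 13 h.

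Both first-hour comparisons used the same 4 dry arrays. With unchanged groups simulated against those arrays 0 probe sets were shared, r across genes was 0.50 against 0.25 observed, and the covariance was 0.0167 against 0.0211. With different dry arrays for the tissues, 2 each, 13 to 21 were shared and r lay between -0.04 and 0.09. The dry part holds both tissues, so a difference between them also enters each change. Without replicate 3 of the 1 h radicle 52 were shared, and 11 on the 12 arrays alone.

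Over the 9 stages, 9409 probe sets changed in micropylar endosperm and 9312 in radicle, 4756 and 4107 of them by at least 2-fold between stage means. Among those 4756, 1351 were highest at 1 h, 763 at 3 h and 825 at 16 h after endosperm rupture. In the radicle 1095 of 4107 were highest at 1 h and 937 at 16 h after endosperm rupture. XTH18 peaked in micropylar endosperm at 7 h with ruptured testa (7.05) and GASA6 at 10 h (8.74), while RAB18 went from 11.79 at 1 h to 4.61 after endosperm rupture.

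Over all comparisons 53 of 336 list tests passed camera, 27 higher and 26 lower, with median, mean and test never differing in sign. With arrays shuffled over all groups as many as 51 passed, so that number alone does not exclude chance. With an estimated correlation 37 of the 53 held, and fry, which asks only whether a list moves 1 way, called all 53. Xyloglucan endotransglucosylases passed in 10 of 16 comparisons and late embryogenesis genes in 9, the latter always lower, or in 9 and 8 with an estimated correlation. Lists that passed in none were the 2 pectin methylesterase inhibitors (lowest adjusted p = 0.645), mannanases, glucanases and polygalacturonases (0.134), NADPH oxidases and antioxidant enzymes (0.0592), the 2 seed coat markers (0.134) and cotyledon and shoot markers (0.0592).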

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

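The tests of AUX1 and SMB alone, and those of the differences between time courses, were chosen only after the result was seen.

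Single arrays stood apart for 28 of 496 pairs of a named gene and a group of 4, the gap to the next array, as a share of the group's range, being over Dixon's 95% critical value, which chance gives in about 1 in 20 groups. In micropylar endosperm at 1 h, replicate 2 was at 4.33 for XTH16 (others 3.39 to 3.49) and 3.43 for CYP707A3 (3.74 to 3.81). At 7 h with intact testa, replicate 1 was at 5.00 for HSP17.4 (5.87 to 6.04) and 7.59 for XTH22 (AT5G57560, 6.72 to 6.82), and replicate 2 at 3.45 for SESA5 (3.06 to 3.12). At 7 h with ruptured testa, replicate 2 was at 5.33 for XTH19 (7.38 to 7.50), 5.57 for ACX1 (6.03 to 6.05) and 7.52 for KAT2 (8.17 to 8.30), and replicate 4 at 5.23 for ABI3 (AT3G24650, 5.72 to 5.80). At 16 h with intact endosperm, replicate 1 was at 5.23 for RAB18 (4.51 to 4.63) and 6.38 for XTH19 (4.57 to 4.72). After endosperm rupture, replicate 4 was at 3.49 for MAN7 (3.61 to 3.63), replicate 1 at 4.89 for ABI5 (4.66 to 4.69) and replicate 3 at 5.84 for LEA7 (3.39 to 3.51).

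In radicle at 1 h, replicate 3 was at 3.32 for XTH4 (3.52 to 3.55), 4.87 for XTH5 (4.37 to 4.43) and 7.87 for ATMG00520 (6.45 to 6.52). At 7 h with ruptured testa, replicate 1 was at 4.05 for MCM7 (3.76 to 3.77) and 4.58 for MCM4 (3.91 to 3.98) and replicate 3 at 4.61 for MCM5 (4.81 to 4.85). At 16 h, replicate 1 with intact endosperm was at 7.13 for ACO1 (5.66 to 5.90) and 5.62 for MCM4 (6.42 to 6.53), while after rupture replicate 2 was at 3.93 for PME3 (AT3G14310, 3.67 to 3.70) and replicate 3 at 7.43 for MCM7 (6.61 to 6.74). In cotyledons at 3 h, replicate 2 was at 3.82 for PME3 (3.34 to 3.41) and 5.40 for ABI5 (6.09 to 6.12). In non-micropylar endosperm, replicate 3 at 3 h was at 6.21 for OLEO1 (7.11 to 7.23) and replicate 1 at 13 h at 5.70 for ABI5 (5.07 to 5.17).

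The response to a stage change differed between tissues for 23 of the reported values, by a test of the difference itself. At testa rupture the difference of micropylar endosperm from radicle was 2.35 for XTH18, 2.21 for XTH6, 0.81 for XTH24, -2.15 for AT5G09970 and -1.45 for ECP63, which in radicle was too dim to show a fall. At endosperm rupture it was 1.23 for WRKY33, 0.91 for XTH30, 1.17 for ADPG2, 2.08 for AT1G78000, 2.03 for AT4G24150, -0.45 for PME44 and -1.35 for MCM7. Before testa rupture it was 5.43 for EXPA2, 3.35 for XTH19, 3.72 for GASA6, -2.17 for EM1 and -2.23 for EPR1, and between the ruptures -5.43 for GASA6 and -0.55 for MAN7. From 3 h to 13 h non-micropylar endosperm differed from cotyledons by 5.95 for EXPA2, at most 4.60 for XTH33, -1.47 for RAB18 and 3.47 for PCK1. Levels under the brightness limit make the values approximate for XTH18, XTH24, WRKY33, XTH30 and PME44 at the ruptures and for EXPA2, XTH19 and GASA6 before testa rupture.

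Root transcripts PIN2, AUX1 and SMB were higher in micropylar than in other endosperm, by at least 0.64, by 0.55 and by at least 0.47. Radicle tissue carried over during dissection is a candidate source. AUX1 was higher in micropylar endosperm than in the radicle samples by 0.26 (SE 0.12). Those samples held radicle with lower hypocotyl, and tissue from the radicle tip alone could differ from their mean, so this does not decide for AUX1. For SMB the same difference was 0.14 (SE 0.08), but its levels of 3.59 and 3.44 are too dim for that to decide, so carry-over stays open. The 6 transcripts at least 8-fold higher in radicle than in non-micropylar endosperm implied a median radicle share of 6.19% (95% bootstrap interval -4.39 to 8.50), while PIN2 alone would need a share above that interval, so for PIN2 carry-over and expression in the cap cannot be told apart with so few transcripts. A root-like programme in the cap stays open as an untested biological explanation.

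Transcripts were higher in micropylar endosperm after each rupture, and 3 explanations were weighed. Of the 506 higher transcripts after testa rupture, 71.5% lay above their radicle level by more than 2 standard errors, as did 87.1% of 464 after endosperm rupture. Radicle tissue left in caps could thus not be the whole cause if it was like the radicle samples, which also held lower hypocotyl. Ruptured seeds at 7 h may instead be further along the time course. Of the 880 testa rupture calls 97.8% had the same sign from 5 h to 10 h, against 71.2% of all probe sets. That interval spans the 7 h harvest, at which testae were rupturing. A signal from rupture would give the same agreement, so the share cannot tell age from rupture. For the 16 h seeds no later stage was sampled, and from 10 h to 13 h the share was 62.4% of 598 against 54.0%. The time-course account could thus be examined in the 7 h seeds alone. A signal from rupture itself stays open because age and rupture were sorted on the same seeds.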

How the results depend on the processing

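The fits with the within-group axis as a covariate and without 4 arrays far from their group mean were chosen only after the results were seen. No named gene reversed direction in any alternative. Of 265 passing values of named genes, all held with a trend and robust moderation, 1 was lost without dim probe sets, 1 with centring, 2 with quantile normalization, 6 with array weights, 44 on the arrays of the comparison alone, 1 with the axis covariate and 2 without far arrays, and 33 lost their call with at least 1 array left out (122 of 1986 refits of a gene). Scaling shifted the median of all probe sets by under 0.1. Signal near background limits dim probe sets: the 748 left out by the brightness limit had no group mean over 3.59.

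With array weights, counts moved by over 1.5 times to 2328 (micropylar endosperm) and 637 (radicle) at testa rupture, 191 for their interaction, 1403 in radicle at endosperm rupture, 3414 in micropylar endosperm between ruptures and 35 in the first hour. On the comparison's own arrays they were 30 and 266 at endosperm rupture, 41 for its interaction and 1454 in micropylar endosperm between ruptures. They were 1793 in cotyledons, 623 in dry parts and 11 in the first hour. Such fits rest on fewer arrays, but groups also differed in spread. In micropylar endosperm the median SD was 0.20 (intact) and 0.19 (ruptured) at 16 h. At 7 h it was 0.13 and 0.15, and there the count rose to 1124. The estimate of the spread shared by all groups does not follow such differences. Without far arrays, 1263 passed in radicle at endosperm rupture. For the others the cause was not tested. On their own arrays 523 of 1124 calls were higher at testa rupture in micropylar endosperm, against 506 of 880, and 27 of 30 at endosperm rupture, against 464 of 598. Other shares that moved were 141 of 191 against 52 of 60 for the testa rupture interaction with array weights, and for the first hour 45 of 113 with the axis covariate and 5 of 11 on its own arrays against 21 of 79.

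A 2-fold minimum left, by its construction, 197 and 70 at testa rupture, 167 and 176 at endosperm rupture, 216 for its interaction, 1558 and 1415 before testa rupture, 492 and 343 between ruptures, 1998 in non-micropylar endosperm, 882 in cotyledons, 546, 59 and 569 between tissues, 301 in dry parts, 8 in the first hour, and 4756 and 4107 over the stages. Of list tests, fry called 143 of 336, being a test against no change rather than against other genes.

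Without 1 array at a time, counts ranged from 464 to 921 (micropylar endosperm) and 111 to 242 (radicle) at testa rupture, 351 to 732 and 502 to 1148 at endosperm rupture, 34 to 75 and 271 to 440 for the interactions, 4719 to 4942 and 4948 to 5337 before testa rupture, 1578 to 2234 and 1240 to 2011 between ruptures, 4994 to 5175 in non-micropylar endosperm, 3052 to 3597 in cotyledons, 1027 to 1253 in dry parts and 52 to 96 in the first hour. Without 1 replicate number they were 8272 to 8585, 1267 to 1582 and 4176 to 4594 between tissues, 8305 to 8448 and 7708 to 8343 over the stages, and 51 to 59 for lists.

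Replicate numbers did not pair the samples: in 0 of 26 pairs of groups did every same-numbered pair correlate over 0.1, the mean correlations lying between -0.30 and 0.23. With the number as a fixed replicate block, 877 and 239 passed at testa rupture and 596 and 767 at endosperm rupture, and with a random block 883, 235, 596 and 755. Taking the best or mean probe set per gene was not run, since each locus has 1.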

Other observations

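Counts over other splits of the samples were chosen only after the result was seen, except those after removal of the shared rupture effect.

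Mitochondrial transcripts, which encode parts of the respiratory chain and its gene expression machinery, had their highest mean at 3 h among the stages sampled in each tissue. Non-micropylar endosperm and cotyledons were not sampled before 3 h, so an earlier peak there could not be seen. In micropylar endosperm the mean at 1 h, 6.04 ± 0.31 (SD, n = 4), was close to that at 3 h. Mean expression of the 47 loci was 5.13 ± 0.07 in whole dry seeds, 6.15 ± 0.22 in micropylar endosperm, 6.07 ± 0.19 in radicle, 6.68 ± 0.24 in non-micropylar endosperm and 6.66 ± 0.31 in cotyledons at 3 h, and 4.44, 4.27, 4.80 and 4.83 at 13 h (SD, n = 4 each). In limma 33, 34, 35 and 36 of the 47 fell from 3 h to 13 h in these tissues, with medians of -1.43, -1.54, -1.25 and -1.96, and 42 were lower in all 4.

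Transcripts of mitochondria may fall relative to nuclear ones as germination proceeds, which is a hypothesis found and tested on the same data. A shift of all probe sets of like brightness could not be the whole cause: the median over the 4 tissues was -1.78, against -0.27 to 0.30 in 10000 nuclear lists matched on level. With the leading axis of the spread within groups as a covariate, 95.1% of the fall was left in non-micropylar endosperm, 103% in cotyledons, 94.7% in micropylar endosperm and 87.9% in radicle. A change in how much organellar RNA the 3' labelling took up stays open, since these data hold no second measurement of it.

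Cell cycle and DNA replication genes were lower in micropylar endosperm than in radicle over the 9 stages in 10 of 16 and higher in 4 (14 adjusted over the list alone), with the sliding clamp PCNA1 (AT1G07370) at -0.98 ± 0.08 and MCM5 at -0.92 ± 0.07, but the list did not pass camera (adjusted p = 0.0749). NADPH oxidases and antioxidant enzymes were higher in 6 of 10 and lower in 3 (10 adjusted over the list alone) and did not pass either (adjusted p = 0.0592).

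Chance was tested by counting calls in other splits of the same arrays. With all 35 splits of 4 against 4 arrays (or 4 against 3), the real split gave the most in each of 11 comparisons, 1 of 35. That is the lowest share 35 splits can give, and it was not adjusted over the 11 comparisons. Chance is thus unlikely for each taken singly, but not excluded. At testa rupture the highest other split gave 288 against 880 in micropylar endosperm and 45 against 237 in radicle. At endosperm rupture the figures were 525 against 598 and 457 against 756. Before testa rupture they were 1356 against 5313 and 1876 against 5494, and between ruptures 1131 against 2212 and 821 against 1648. From 3 h to 13 h they were 2209 against 5459 in non-micropylar endosperm and 2341 against 3529 in cotyledons, and in dry parts 803 against 1340.

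With 100 random splits, chance is unlikely for micropylar endosperm against radicle (highest other 695 against 9137) and against other endosperm (316 against 1895). The same holds for radicle against cotyledons (3659 against 5118) and for the stage profiles (5112 against 9409 and 4796 against 9312), each with 1 of 100. List calls also had 1 of 100, but arrays shuffled over all groups gave as many as 51 against 53. With the preset correlation nearly as many lists can thus pass without the real groups, so their number does not exclude chance. In the first hour 4 of 100 splits gave at least 79, which speaks only narrowly against chance. The highest other gave 222. Labels were shuffled over both tissues and the dry part, so differences between these groups can enter such splits. For the interactions chance could not be excluded by the first splits. At testa rupture 5 of 100 reached 60 (highest other 257), and at endosperm rupture 6 of 100 reached 370 (highest other 1126). The highest of these splits gave several times the real count. Rupture labels were shuffled within each tissue, which can turn the shared rupture effect into a difference between tissues. After removal of that shared effect 1 of 100 splits reached the real count in each, with highest others of 22 and 297, so chance is unlikely.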
